A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

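The deposited files are lists of ATAC-seq peaks, 1 for each of 14 libraries, 8 from the mouse iMGT-Myh6-eGFP-MEF line and 6 from the human iMYOD-IMR90 line. Per the labels' protocols, 300000 cells per well were transfected with siRNA on the day before doxycycline was added at 1 µg/mL (mouse) or 100 ng/mL (human), and about 250000 cells per condition were frozen at day 1 and made into libraries with a commercial ATAC-seq kit. Per the submitters' processing notes, the tools were Bowtie2 and MACS3 and the builds mm10 and hg38. Their versions, the treatment of duplicate and mitochondrial reads, any shift of reads for the Tn5 insertion and any list of excluded regions are not given in the sources used here. Peaks were called per library, so replicates are separate lists. The authors' deposited lists hold for each peak a score, a fold enrichment over background (a linear ratio), a p-value and a q-value as −log10, and a summit position. The deposited −log10 q starts at 2.00 to 2.04 in every list, which corresponds to q of 0.01. A score, fold or p of a peak is the authors' own value and served only to describe, rank or filter peaks within a list. Ground-state libraries carry a treatment label that names induction, while their time label and the series design give the ground state without reprogramming, and they were kept as ground state. The labels call the 2 libraries of each group biological replicates without saying what was kept separate, so spreads between them may be partly technical. No 2 libraries held identical lists.

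Read counts were not used here. The background level of each library was recovered from the deposited fold and −log10 p of 2000 sampled peaks with −log10 p under 60, taking the fold as (pileup + 1)/(background + 1) and the p-value from the Poisson distribution. A whole number of reads fitted within 0.01 of the deposited −log10 p for 100% of these peaks in every library. The first percentile of background, divided by the narrowest peak, gave reads per kb, which rests on that formula and serves as a relative depth. A shallower library gives fewer and weaker peaks, and absence of a peak is not absence of accessibility.

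Peaks on autosomes and X were kept, which left out 0.119 to 0.153% of peaks per mouse library and 0.293 to 0.339% per human library. Overlapping peaks (at least 1 bp) of all libraries of a line were merged into regions. A region counted as gained where both libraries of the first group and neither of the second had a peak, and as lost in the reverse case. The same count in the other 2 splits of the 4 libraries served as the level without a group difference. Library pairs were compared by the Jaccard index, with an exact permutation test over all pairings.

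Mouse regions were assigned to protein-coding genes of the GRCm38.p6 annotation (the assembly of mm10, 21631 genes), by the gene span that held the midpoint or else the nearest gene end within 100 kb, which covered 91.9% of regions. The table used gives no strand, so transcription start sites were not determined and "gene end" means within 1 kb of either end of a span, in place of the promoter class planned. As a check of the build, 12.4% of regions lay within 1 kb of a gene end, and 4.96% after a shift by 100 kb. Exons, introns and untranslated parts were not annotated. All members of 20 gene lists matched the annotation, or did so through a synonym, as did 21 of the 25 of the interferon list, and lists were tested by Fisher's exact test of gained and lost regions of the list against those of all other assigned genes, two-sided, with Benjamini-Hochberg adjustment over the 21 lists of a comparison and a threshold of 0.05. On simulated calls at the regions of the MGT comparison (17225 genes), an odds ratio of 4 planted in the cardiac muscle list was called in 85 of 100 draws, and with no shift some list was called in 3 of 100. At the regions of the mouse siJunb comparison the planted list was called in 4 of 100 draws. These draws set each region independently, so they leave out the likeness of regions of 1 gene. Planted region changes were all recovered, an outcome fixed in advance, since every planted change was called in both libraries of its group.

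Named regions followed a rule fixed in advance. For MGT induction and each mouse knockdown, these were in each direction the 5 gene-end and 5 distal regions with the highest lower percentile of −log10 p over the 2 libraries, 1 per gene and without predicted genes. Up to 2 members per direction were taken from each list, and Junb, H1f0, Mef2c, Gata4, Tbx5 and Myh6 in any case. For the human knockdowns these were 4 gained and 4 lost regions. The text names a part of these regions and list members. Motif tests in both lines and gene lists in the human line were planned and not run, since genome sequence and human annotation were not used here. Alternatives were a stricter −log10 q of at least 5, equal numbers of top peaks per library, peaks covering 50% of a region, absence of any peak within 500 bp, regions merged over 4 libraries, leaving out each library, the replicate number as a block, genes as the unit, a split by gene ends, and assignment within 20 kb. A minimum fold of 6, crossed replicate numbers, all 4 mouse knockdown libraries together and the splits of the 6 mouse day 1 libraries were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.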

Results

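Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 14 libraries from 2 fibroblast lines that carry doxycycline-inducible lineage factors. The mouse line is an embryonic fibroblast line with inducible Mef2c, Gata4 and Tbx5 (MGT), 3 cardiac transcription factors, and a green fluorescent reporter of Myh6, the gene of the cardiac alpha myosin heavy chain. The human line is IMR90, an established fetal lung fibroblast line, with inducible MYOD, the transcription factor that starts the skeletal muscle programme. Cells were transfected with a control siRNA or with an siRNA against Junb, a subunit of the AP-1 transcription factor, or H1f0, which encodes the linker histone H1.0. The 8 mouse libraries form 4 groups of 2, namely the ground state with control siRNA and day 1 of MGT induction with siControl, siJunb or siH1f0. The 6 human libraries form 3 groups of 2, all at day 1 of MYOD induction, with siCTRL, siJUNB or siH1F0. A human ground state is not analysed here. The labels give 50 M reads for each library and number the 2 libraries of a group as biological replicates.

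Mouse libraries held 70783 to 80802 peaks on the autosomes and X, covering 36.1 to 42.8 Mb, and human libraries held 59760 to 88006 peaks covering 29.9 to 46.3 Mb. The number of peaks per library was 79401 ± 671 in mouse siControl, 77970 ± 1326 in siJunb, 78955 ± 2612 in siH1f0 and 71664 ± 1246 in the ground state (mean ± SD, n = 2 each). In the human line it was 66859 ± 10039 in siCTRL, 85735 ± 3212 in siJUNB and 81131 ± 2160 in siH1F0 (n = 2 each). The background read level recovered from the peak values, a measure of relative depth, was 8.32 to 11.002 reads per kb in the mouse libraries. It was 9.12 ± 1.13 in the ground state and 10.6 ± 0.322 in siControl (mean ± SD, n = 2 each). In the human libraries it was 3.98 and 4.002 reads per kb in the siCTRL libraries and 4.52 to 5.81 in the knockdown libraries. Merging overlapping peaks gave 115288 mouse regions, of which 44730 had a peak in all 8 libraries, and 107573 human regions, of which 51180 had a peak in all 6.

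The mouse libraries labelled siJunb and siH1f0 did not pair as their labels say. The Jaccard index, the share of regions common to a pair of libraries, was 0.808 between the siControl libraries and 0.812 between the ground-state libraries, but 0.751 between the libraries labelled siJunb and 0.753 between those labelled siH1f0. It was 0.796 between siJunb replicate 1 and siH1f0 replicate 2, and 0.805 between siJunb replicate 2 and siH1f0 replicate 1. With the siControl libraries, siJunb replicate 2 and siH1f0 replicate 1 stood at 0.782 to 0.785, above the knockdown pairs as labelled. For siJunb replicate 1 and siH1f0 replicate 2 the values with siControl were 0.741 to 0.748. Labelled pairs averaged 0.781, and 4 of the possible pairings of the 8 libraries reached that value (exact permutation test, one-sided p = 0.0381). All of these kept the ground-state pair, and some paired each siControl library with a knockdown library. The p-value therefore does not speak for the labels of the knockdown libraries. The pairing with the highest mean, 0.805, kept the siControl and ground-state pairs and crossed the knockdown libraries. The groups below are those of the labels, and every mouse result for a single knockdown concerns the libraries labelled so. Human libraries averaged 0.741 within labelled pairs, the highest of the 15 pairings, which gives the smallest p this design allows (exact permutation test, one-sided p = 0.0667). Human siCTRL replicate 2 had the lowest indices with the other libraries, at 0.642 to 0.704. It also had the fewest peaks, 59760, and a short list by itself limits the index with longer lists. How much of the low values list length accounts for was not examined. The siCTRL pair, at 0.704, was less alike than siCTRL replicate 1 with each knockdown library (0.719 to 0.747), and siJUNB replicate 2 with siH1F0 replicate 1 (0.770) or 2 (0.765) was more alike than the siJUNB pair (0.757) and the siH1F0 pair (0.761).

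**Figure D1:**
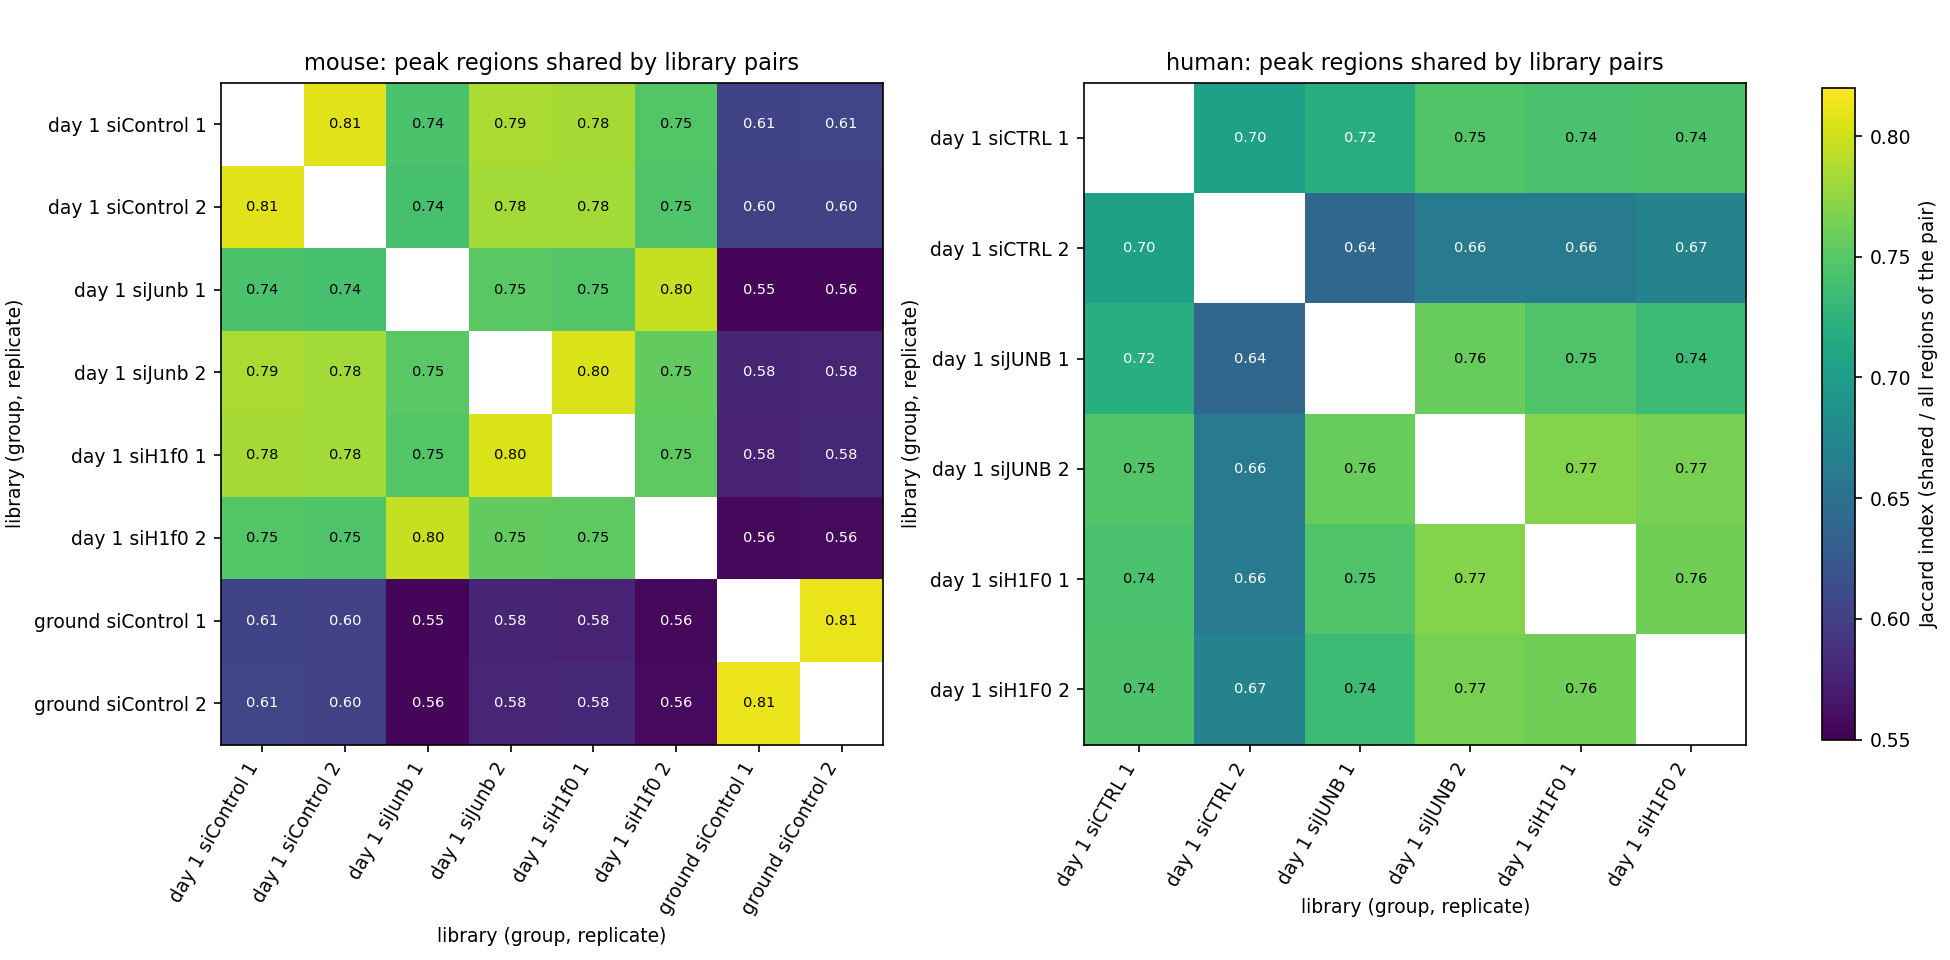
Jaccard index of merged peak regions for each pair of libraries, mouse on the left and human on the right, with group and replicate on both axes and colour giving the index. The 2 crossed pairs of mouse siJunb and siH1f0 libraries stand at 0.796 and 0.805, above the labelled pairs at 0.751 and 0.753. Human siCTRL replicate 2, the human library with the fewest peaks, forms a band of low values.

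The first comparison asks how chromatin changed by day 1 of MGT induction, with control siRNA in both groups. The groups differ in MGT, doxycycline and day together, so the parts of these cannot be told apart. At Myh6, a region from 54967344 to 54968759 on chromosome 14 (mm10) at 1 end of the gene had no peak in either ground-state library and a peak in both siControl libraries, with fold enrichments of 9.74 and 8.12. The cells carry a Myh6 reporter, so reads from reporter copies cannot be told from reads of the gene. Mef2c gained 6 of its 22 regions and lost none. One of the 6 lay inside the gene on chromosome 13 from 83565710 to 83566671, with fold enrichments of 14.6 and 13.3. Gata4 lost 2 of its 15 regions and gained none, and Tbx5 had 4 regions of which none changed. The cells also carry inducible Mef2c, Gata4 and Tbx5, and whether reads from those copies add to peaks at these genes was not checked. The Nkx2-5 locus, which encodes a homeodomain factor of early heart development, gained 2 regions and lost none.

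Across the genome, 14724 regions were gained on induction, with a peak in both siControl libraries and in neither ground-state library, and 7555 were lost. Splitting the same 4 libraries in the other 2 ways gave 1332 and 1314 changed regions, against 22279 for the labelled split. With 2 libraries per group an exact permutation test cannot go below p = 0.333, so no p-value is given for these counts. Gained regions made up 66.1% of those changed, and 55.4% when every library was reduced to the same number of peaks. That setting itself balances gained and lost regions, so the part of the lower mean ground-state depth in the excess of gained regions cannot be told. Of the gained regions 3.65% lay within 1 kb of an end of a protein-coding gene (95% exact binomial interval 3.36 to 3.97), and of the lost regions 3.90% (3.48 to 4.37), against 21.6% of the 50908 regions present in all 4 libraries. The gained regions included 3326 that lay above the median peak of their own library in both siControl libraries, and the lost regions 601 in the ground-state libraries. Leaving out ground-state replicate 1 raised the lost regions to 12032, since only 1 library then had to show the peak.

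The strongest gained regions at gene ends lay at Atp6v0a1, a subunit of the vacuolar proton pump, at Zfp275, at Mrpl51, at Lmod3, which encodes a leiomodin of striated muscle thin filaments, and at Bmp1, the procollagen C-proteinase. Their fold enrichments in the 2 siControl libraries ran from 7.92 at Bmp1 to 17.7 at Lmod3. The Lmod3 region spans 97252276 to 97253368 on chromosome 6, inside the gene. The strongest distal gained regions were assigned to Atp8b4, Cct8, Otulin, Srrm2 and Zfp459, with fold enrichments between 15.4 and 26.1. Among lost regions, those at gene ends with the highest rank lay at Ifrd1, Il23a, Cyp4v3, Gchfr and Rtkn2, and those farther away at Tra2a, Enpp1, Ywhag, Sod3 and Elk3. The Tra2a region, from 49236451 to 49236616 on chromosome 6, had fold enrichments of 43.1 and 44.9 in the ground-state libraries and no peak at day 1. It was as narrow as the narrowest peak of those libraries (165 bp). No list of excluded regions was applied here, so this region calls for caution. Il23a encodes a subunit of interleukin 23, Sod3 the extracellular superoxide dismutase and Elk3 an ETS factor that responds to serum.

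Of 21 gene lists fixed before the data were examined, the cardiac muscle list had a shifted ratio of gained to lost regions. Its 30 genes had 47 gained and 7 lost regions, an odds ratio of 3.34 against other genes (95% exact interval 1.498 to 8.76, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0254). Among the 30 members, 12 had gained regions alone, 3 lost regions alone, 2 both and 13 neither. Rbm20, a splicing factor of titin, gained 9 regions and lost none, and Cacna1c, the pore subunit of the cardiac L-type calcium channel, gained 10 and lost 2. Nppa, which encodes atrial natriuretic peptide, lost 2 and Ryr2, the cardiac ryanodine receptor, lost 1, with none gained. Regions of 1 gene are not independent, and with genes as the unit the adjusted p was 0.0798 (10000 random lists with the same numbers of changed regions per gene). The adjusted p was 0.137 without ground-state replicate 1 and 0.476 without ground-state replicate 2, 0.0954 with the stricter peak threshold, 0.454 with a minimum fold enrichment of 6, and 0.147 where peaks had to cover 50% of a region. The odds ratio was 1.90 without ground-state replicate 1, 1.75 without ground-state replicate 2, 1.99 with the minimum fold, 2.16 with 50% cover, and 1.74 with replicate number as a block.

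The fibroblast identity and extracellular matrix list went the other way, with 36 gained and 34 lost regions, an odds ratio of 0.524 (0.318 to 0.864) that did not pass correction (Fisher's exact test, adjusted p = 0.0779). Col6a3 lost 5 regions and gained 1, and Mmp2, a gelatinase, lost 4 and gained none, while Col5a1 gained 5 and Fbln2 gained 4 with none lost. With replicate number as a block its adjusted p was 0.00641 (Mantel-Haenszel test) and its odds ratio 0.633. That test counts a region changed at both replicate numbers in each block, so its p-values are too small. The list passed with no peak allowed within 500 bp (Fisher's exact test, 0.0475). It did not with 50% cover (0.473), the minimum fold (0.492), assignment within 20 kb (0.558) or genes as the unit (random lists, 0.136). The odds ratio was 0.523 and 0.517 without siControl replicate 1 and 2, and 0.577 and 0.745 without ground-state replicate 1 and 2. Neuronal genes had 17 gained and 18 lost regions (odds ratio 0.468, Fisher's exact test, adjusted p = 0.207). They passed with the block (Mantel-Haenszel test, 0.00641, odds ratio 0.530), where the same limit holds, and with 50% cover (Fisher's exact test, 0.0244). They did not with the stricter threshold (0.0999), the minimum fold (0.454), assignment within 20 kb (0.558) or genes as the unit (random lists, 0.263). The cardiac transcription factor list had 21 gained and 7 lost regions, the skeletal muscle list 13 and 2, and the smooth muscle list 25 and 10, none of which passed. Gained and lost regions numbered 54 and 22 for TGF-beta and myofibroblast genes, 47 and 22 for YAP and TEAD targets, 29 and 18 for AP-1 and serum responsive genes, and 27 and 15 for inflammatory genes. They numbered 29 and 15 for senescence and ageing, 13 and 8 for the cell cycle, 6 and 7 for the AP-1 family, 0 and 1 for linker histones, and 5 and 6 for interferon response. Marker lists of other cell types gave 14 and 8 for epithelial, 23 and 11 for endothelial, 16 and 6 for blood and macrophage, and 11 and 4 for pluripotency genes. HOX genes gave 6 and 1, and the housekeeping control list 9 and 4. For the lists of this paragraph other than fibroblast and neuronal genes, adjusted p-values of the exact test ran from 0.686 to 1.

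**Figure D2:**
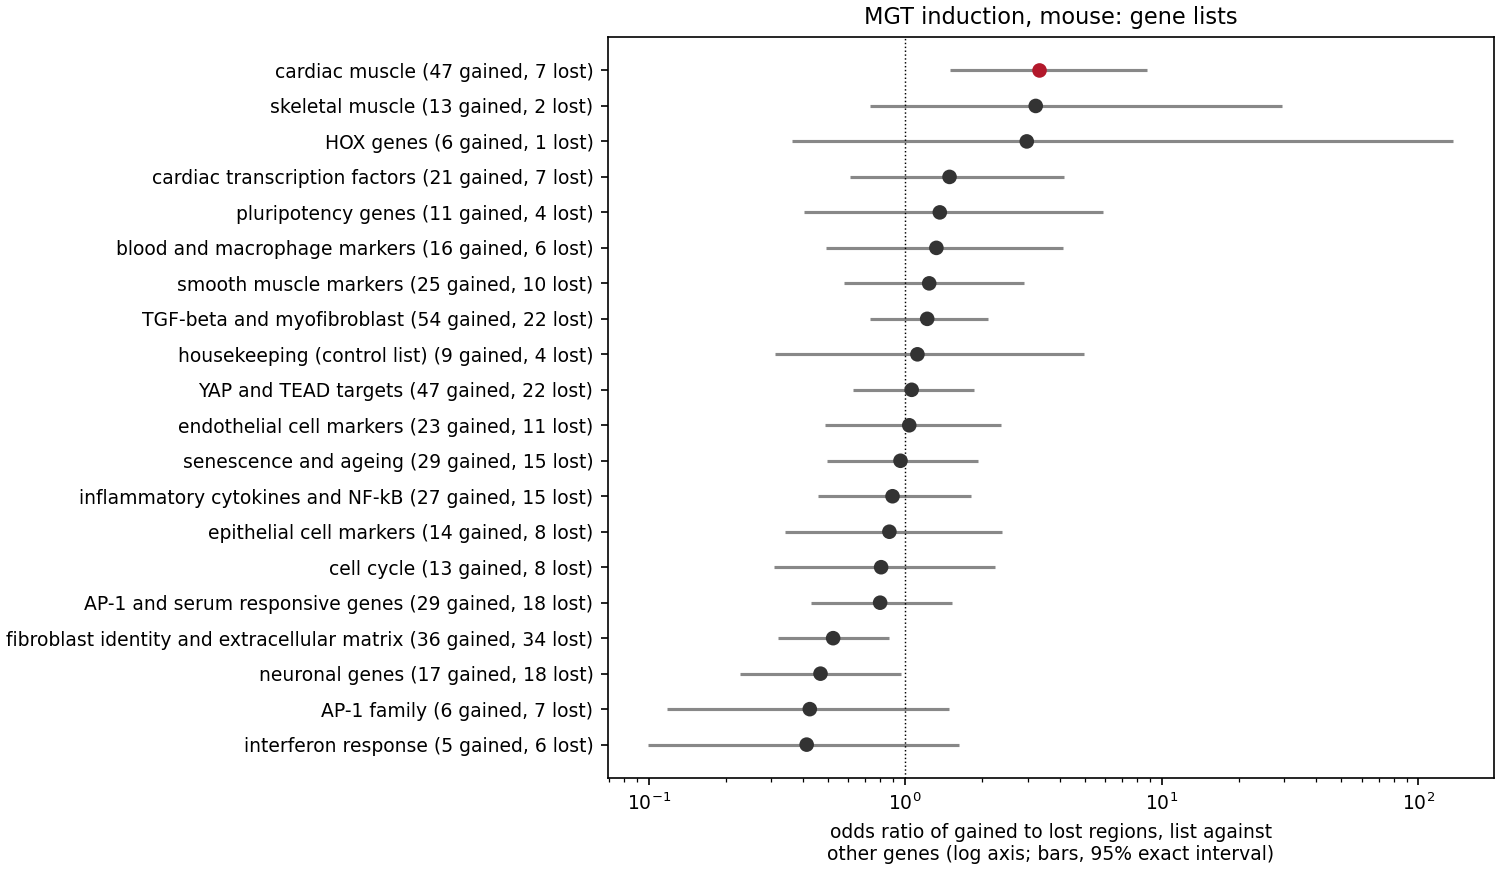
Odds ratio of gained to lost regions on MGT induction for each gene list against all other genes, on a log axis, with 95% exact intervals; linker histones, with no gained region, are left out. The red point is cardiac muscle at 3.34, the list with adjusted p = 0.0254 in the exact test, and fibroblast identity lies at 0.524. For cardiac muscle the adjusted p was 0.0798 with genes as the unit (random lists). Its odds ratio was 1.90 or 1.75 without ground-state replicate 1 or 2.

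The next comparisons ask what knockdown of Junb or of H1f0 changed at day 1 of MGT induction. Of 4 regions assigned to Junb, 3 had a peak in all 8 libraries, and both regions of H1f0 did. At 1 of the H1f0 regions the fold enrichment was 12.6 and 13.5 in the ground state and 7.48 to 10.1 at day 1. At the other it was 10.1 and 11.5 in the ground state and 9.17 to 11.3 at day 1. The median fold of all peaks was also higher in the ground-state libraries (10.7 and 10.9) than at day 1 (8.81 to 9.52). These fold values therefore do not show a change at H1f0. Peaks at these loci do not measure RNA, so they do not check the knockdown or the labels.

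With siJunb, the strongest gained regions at gene ends lay at Skil, a repressor of TGF-beta signalling, Orai3, Rbpj, the DNA-binding partner of Notch, Nsl1 and Bex2. Distal gained regions of highest rank were assigned to Tmigd1, Arid1b, a subunit of the BAF remodelling complex, Ift74, Kif14 and Frmd5. The Arid1b region, from 5201973 to 5202346 on chromosome 17 inside the gene, had fold enrichments of 9.11 and 9.88. Lost regions at gene ends lay at Esyt2, Prss32, Sox12, Unk and Nrgn, and distal ones at Rhod, Rnf214, Rgma, Bcl3 and A26c3. In all, 1789 regions were gained and 2586 lost in the libraries labelled siJunb against siControl. The other 2 splits of these 4 libraries gave 2784 and 2782 changed regions against 4375, a ratio of 1.57 to their mean. Most of the changed peaks were weak, with a median percentile of 9.16 among the peaks of their library for gained and 10.95 for lost regions. Without any 1 of the 4 libraries the gained regions numbered 3460 to 7132 and the lost 4816 to 7304, since fewer libraries then had to agree. Without siJunb replicate 1 gained regions outnumbered lost ones, 5667 to 4816. Leaving out a siJunb library asks gained regions for fewer peaks and lost regions for fewer absences, so this turn may come from the setting alone.

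Among the fixed lists with siJunb, YAP and TEAD targets had 9 gained and 7 lost regions, with 4 members gained only and 6 lost only. Wwtr1, which encodes TAZ, and Tead1 had 3 gained and no lost regions each, and Yap1 and Nt5e 1 lost and none gained each. Fbn1, which encodes fibrillin 1, had 2 lost regions, Col5a1 3 lost and 1 gained, and Smad3 2 lost. Mef2c and Gata4 lost 1 region each and Myl4 and Ttn gained 1 each. None of the 21 lists passed correction and 0 had an unadjusted p under 0.05 (Fisher's exact test). The cardiac muscle list had 9 changed regions, and a simulated odds ratio of 4 in that list was called in 4 of 100 draws, so a shift of this size was rarely detectable there. The other lists were not simulated.

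With siH1f0, gained regions at gene ends lay at Rhebl1, Bex2, Cxcl3, Capn8 and Fam174c, and distal ones included those assigned to Tmigd1, Arid1b, Emp1 and Frmd5. The Bex2, Tmigd1, Arid1b and Frmd5 regions are those also named for siJunb. Lost regions at gene ends lay at Esyt2, Lrrc74a, Usp6nl, Tnk2 and Sox12, and distal ones at Ece1, the endothelin converting enzyme, Zfp74, Flnc, which encodes the muscle filamin, Tmco1 and Ipmk. The Ece1 region, from 137835921 to 137836289 on chromosome 4 outside the gene, had fold enrichments of 17.0 and 16.8 in the siControl libraries. In total 1917 regions were gained and 2326 lost in the libraries labelled siH1f0, 4243 changed regions against 2751 and 2768 in the other splits. Without any 1 of the 4 libraries the gained regions numbered 3758 to 6989 and the lost 4291 to 6981. Gained regions outnumbered lost ones without siH1f0 replicate 2, 6517 to 4291, and were level with them without siH1f0 replicate 1, 6989 to 6981. As with siJunb, leaving out a knockdown library may by itself move the balance this way.

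With siH1f0, YAP and TEAD targets had 8 gained and 6 lost regions, with 3 members gained only and 5 lost only. Tead1 had 3 gained and no lost regions and Wwtr1 3 gained and 1 lost, while Myof and Nt5e had 1 lost and none gained each. Other list members included Grhl2, an epithelial transcription factor, with 3 gained and none lost. Foxa2 gained 2 regions, Tet1 2 and Nanog 1, while Cacna1c lost 2 and gained 1 and Tgfbr3 lost 2. No list passed correction, and 1 list, the pluripotency genes with 4 gained and no lost regions, had an unadjusted p under 0.05 (Fisher's exact test, p = 0.0496, adjusted p = 0.567). The share of regions within 1 kb of a gene end was 6.71% of gained and 3.79% of lost regions with siJunb (odds ratio 1.83, Fisher's exact test over regions, p = 1.99e-05) and 6.57% and 3.14% with siH1f0 (odds ratio 2.17, p = 1.70e-07). These p-values take regions as independent, the comparisons share both siControl libraries and 704 gained and 1181 lost regions, and other splits of the libraries were not examined for this share.

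The next comparison sets the libraries labelled siJunb against those labelled siH1f0. Regions gained in siJunb against siH1f0 numbered 944 and regions lost 1205, together 2149, where the split by replicate number gave 2069 and that by crossed replicate numbers 6872. Without any 1 of these 4 libraries the gained regions numbered 2799 to 4895 and the lost 3498 to 5936, with more gained than lost without siJunb replicate 1 (4725 and 3498) or 2 (4895 and 3974). Leaving out a siJunb library may by itself move the balance this way. Against siControl, 704 gained regions were common to both knockdowns, 39.4% of those of siJunb and 36.7% of those of siH1f0. Lost regions in common numbered 1181, which is 45.7% and 50.8%. Libraries simulated with no group difference, which share the controls, had 414 gained and 553 lost regions in common on average over 200 simulations, with 464 and 609 as the highest. The values for independent lists, 33.2 and 58.3, are too low as a reference, since the controls are shared. The simulation treats the 6 libraries as alike and leaves out the likeness of the crossed pairs, so it sets no bound. Setting siJunb replicate 1 and siH1f0 replicate 2 apart from the other 4 day 1 libraries, a split that follows no label, separated more regions (2026 and 1479). Without siControl replicate 1 the regions in common were 1918 gained and 3667 lost, and without siControl replicate 2 1710 and 3769. Both lists rest on the same 2 control libraries, which by itself gives overlap. The shared regions are those that separate all 4 knockdown libraries from both siControl libraries, and a swap of labels between the knockdowns would leave them as they are.

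Regions lost in all 4 knockdown libraries were assigned most often to Gmds and Ralgapa2, each with 4 lost and none gained, and regions gained in all 4 to Wwtr1, Trim24 and Adarb1, each with 3 gained and none lost. These 5 genes were chosen after their values were seen. Of the 1181 regions lost in all 4, 46.1% had a peak in both ground-state libraries and 43.3% in neither. Of the 704 gained in all 4, 12.4% had a peak in both ground-state libraries and 75.0% in neither. The regions that set siJunb replicate 1 and siH1f0 replicate 2 apart had the same kind of imbalance. Of the 2026 regions with a peak in the other 4 day 1 libraries alone, 51.5% had a peak in both ground-state libraries, against 6.15% of the 1479 found in that pair alone.

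**Figure D3:**
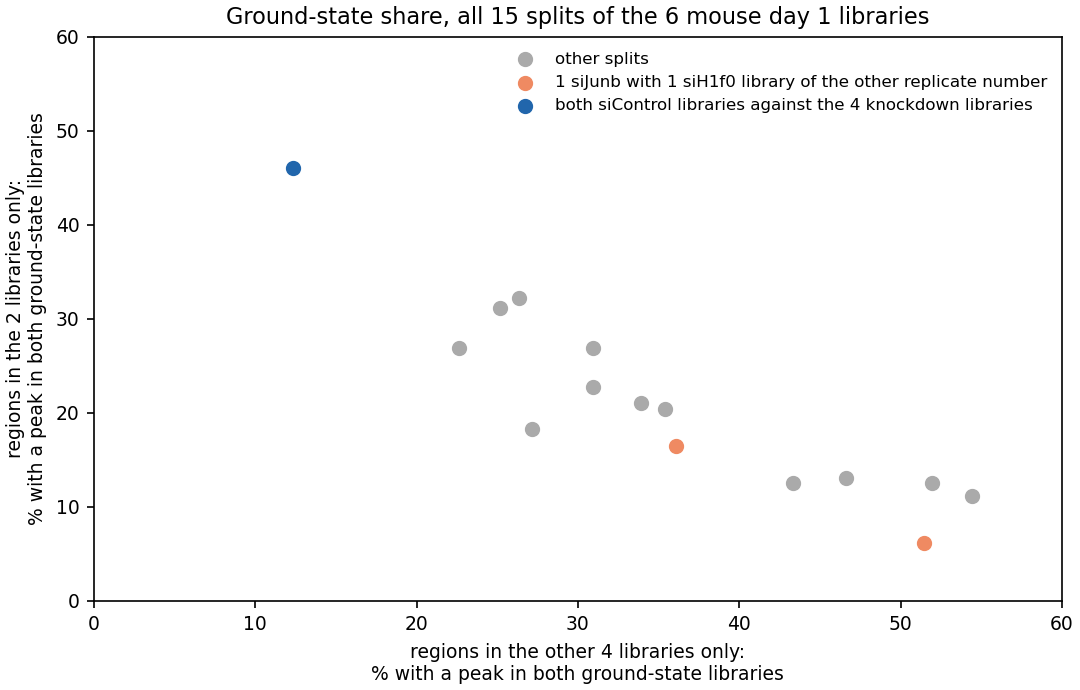
Each point is 1 of the 15 ways to split the 6 mouse day 1 libraries into 2 and 4. The vertical axis gives the percentage with a peak in both ground-state libraries among regions found in the 2 libraries only, the horizontal axis the same among regions found in the other 4 only. The split into siControl and knockdown libraries lies at 46.1% and 12.4%, and the highest of the other splits is at 32.2% on the vertical axis and at 54.5% on the horizontal axis.

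Most regions gained on MGT induction were also open with either knockdown. Of the 14724, both siJunb libraries had a peak in 75.8% (95% exact binomial interval 75.1 to 76.5) and neither in 7.08% (6.67 to 7.51). Both siH1f0 libraries had a peak in 76.8% (76.1 to 77.5) and neither in 6.68% (6.28 to 7.09). Single libraries had a peak in 81.4% and 87.3% with siJunb and in 88.3% and 81.9% with siH1f0. By label the replicates differed more than the knockdowns did, but by the crossed pairs the values are 81.4% and 81.9% for 1 pair and 87.3% and 88.3% for the other, so with a swap of labels the order would turn. The Myh6 region had a peak in all 4 knockdown libraries, with fold enrichments of 10.3 to 12.7. By contrast, 1 of the 6 gained Mef2c regions, from 83585409 to 83585877 on chromosome 13, had none in either siJunb library. That region had none in siH1f0 replicate 1 either, so its absence is not particular to siJunb. The gained Mef2c regions that start at 83592770 and 83739971 had none in siJunb replicate 1. Of the 7555 regions lost on induction, neither siJunb library had a peak in 85.3% (84.5 to 86.1) and neither siH1f0 library in 84.2% (83.3 to 85.0). The selection on siControl libraries lowers agreement in the other groups. Selected in reverse, regions gained with siJunb against the ground state had a peak in both siControl libraries in 77.8% of 14351 cases, and those gained with siH1f0 in 76.7% of 14737. Regions lost with siJunb against the ground state numbered 9443, of which 12.7% had a peak in both siControl libraries, and with siH1f0 9155, of which 11.6% had one. In the forward direction 2.93% of lost regions had a peak in both siJunb libraries and 3.22% in both siH1f0 libraries.

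**Figure D4:**
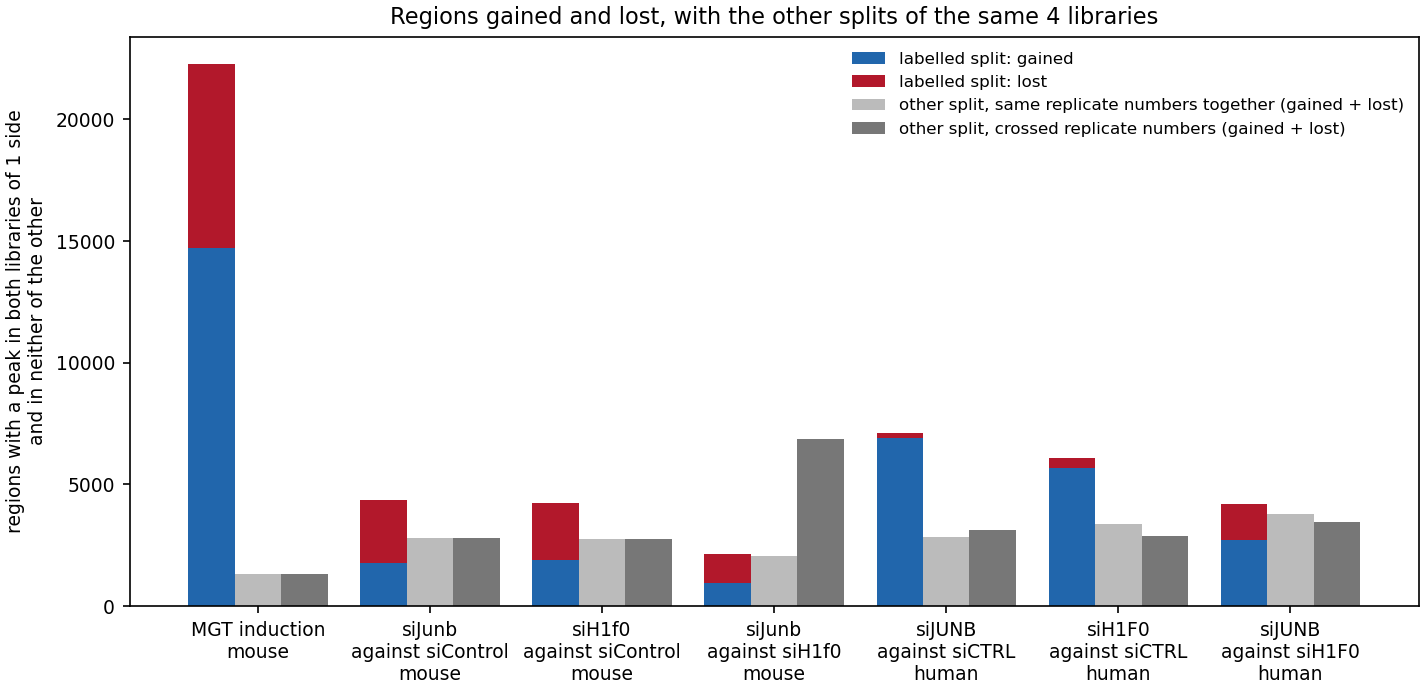
Number of regions gained (blue) and lost (red) in each comparison of 2 against 2 libraries, beside the sum of both for the other 2 splits of the same 4 libraries (grey). MGT induction stands at 22279 against 1332 and 1314, and siJunb against siH1f0 in the mouse at 2149 against 6872 for crossed replicate numbers.

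In the human line, the comparisons ask what JUNB or H1F0 knockdown changed at day 1 of MYOD induction. Human regions are given by hg38 position, since no human gene annotation was used here, and the JUNB, H1F0 and MYOD1 loci were not looked up. With siJUNB the strongest gained regions were from 42254946 to 42255304 on chromosome 19, from 176185039 to 176185423 on chromosome 4, from 65318905 to 65319289 on chromosome 15 and from 73825668 to 73826005 on chromosome 14. Their fold enrichments in the 2 siJUNB libraries were 13.1 and 11.8, 26.4 and 22.4, 12.7 and 11.6, and 22.3 and 21.9. The strongest lost regions were from 76980020 to 76980362 on chromosome 13, from 19984261 to 19984706 on chromosome 22, from 19660105 to 19660492 on chromosome 11 and from 113599701 to 113600062 on chromosome 9, with fold enrichments of 6.00 to 13.7 in the siCTRL libraries. In all, 6890 regions were gained and 223 lost, 7113 changed regions against 2825 and 3148 in the other splits. Gained regions were thus 96.9% of those changed, but 55.02% with equal numbers of peaks per library, where 1716 were gained and 1403 lost. Without siCTRL replicate 2 the counts were 9249 gained and 3296 lost, without siCTRL replicate 1 17551 and 963, and without siJUNB replicate 1 or 2 13400 and 853 or 16338 and 964.

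With siH1F0 the strongest gained regions were from 24485310 to 24485580 on chromosome 2, from 6782305 to 6782762 on chromosome 4, from 177197407 to 177197993 on chromosome 3, and the chromosome 4 region at 176185039 that was also named for siJUNB. Their fold enrichments in the siH1F0 libraries ran from 8.29 to 23.4. The strongest lost regions were from 816394 to 816658 on chromosome 7, from 32462632 to 32463107 on chromosome 5, from 89489214 to 89489527 on chromosome 16 and from 41281135 to 41281492 on chromosome 4, with fold enrichments of 4.80 to 18.9 in the siCTRL libraries. In all, 5676 regions were gained and 398 lost, against 3383 and 2884 changed regions in the other splits. Gained regions were 93.4% of those changed and 57.5% with equal numbers of peaks, where 1740 were gained and 1287 lost. Without siCTRL replicate 2 the counts were 7603 gained and 4064 lost, without siCTRL replicate 1 15484 and 1536, and without siH1F0 replicate 1 or 2 11728 and 1517 or 13306 and 1101.

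Between the 2 human knockdowns, 2721 regions had a peak in both siJUNB and neither siH1F0 library and 1474 the reverse, together 4195 against 3770 and 3473 in the other splits. Without any 1 of these 4 libraries the gained regions numbered 5490 to 9781 and the lost 3650 to 5779, with more lost than gained without siH1F0 replicate 2 (5490 and 5779), and with equal numbers of peaks 1140 were gained and 1192 lost. Leaving out a siH1F0 library may by itself favour lost regions. Against siCTRL, 2804 gained regions were common to both knockdowns, 40.7% of those of siJUNB and 49.4% of those of siH1F0, and lost regions in common numbered 70. Both lists rest on the same 2 control libraries. The simulation with no group difference gave 530 gained and 644 lost regions on average, with 577 and 714 as the highest, and the values for independent lists, 364 and 0.825, again leave out the shared controls. The 70 lost regions lie far below it, and the simulation leaves out the unequal numbers of peaks, so neither count is set against chance here. With equal numbers of peaks the common regions were 686 gained and 590 lost, and without siCTRL replicate 1 they were 10544 and 556, and without siCTRL replicate 2 4292 and 1850.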

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

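The stricter threshold, equal numbers of peaks and leaving out a library were planned, while the fold minimum, the limit at the median peak and the use of any of them to weigh these patterns were chosen after the results were seen. The siJunb libraries minus the control libraries differed by -1431 peaks on average in the mouse line and by 18876 in the human line, with both siJunb libraries below both controls in the mouse and above both in the human. The mouse order rests on 78907 against 78926 peaks and did not hold with the stricter threshold (74697 against 74408) or the fold minimum (60293 against 59199 and 57528), and the mouse difference was about the SD of the siJunb libraries (1326). The difference between the lines was not tested. In the mouse, regions above the median peak gained with siJunb numbered 29 and with siH1f0 24, against at most 26 and 28 in the other splits. Peaks on unplaced contigs, which no comparison used, averaged 258 per library in human siJUNB and 208.5 in siCTRL.

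In the human line, regions gained with either knockdown outnumbered regions lost, and among regions above the median peak of their library 221 were gained with siJUNB and 158 with siH1F0, where the highest count in the other splits of the same libraries was 72; where absence from siCTRL replicate 1 or replicate 2 sufficed, they numbered 459 or 1403 with siJUNB and 338 or 1129 with siH1F0. Those splits put a siCTRL library on each side, so they do not exclude the lower depth of the siCTRL libraries as a source of these regions. Over all changed regions, the gained share with siJUNB was 55.02% with equal numbers of peaks, but that setting itself balances gained and lost regions, so lower depth and a gain of accessibility cannot be told apart. Without siCTRL replicate 2, the library with the fewest peaks and the lowest Jaccard indices, the gained share was 65.2% with siH1F0 and 73.7% with siJUNB. Leaving out 1 library between the knockdowns gave at most 70.5%, but that was without siJUNB replicate 2, of the first group. Without siH1F0 replicate 1 or 2, of the second group as siCTRL is, the share was 56.8% or 48.7%, below both values. The siCTRL replicate 1 library was also shallower than the knockdown libraries. The part of 1 outlying control therefore stays open, as does a biological effect of either siRNA.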

How the results depend on the processing

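Leaving out a library, which by construction raises counts since fewer libraries must agree, was planned, and the fold minimum of 6 and the crossed replicate numbers were chosen after the data were seen. The balance of gained and lost regions turned in every comparison between day 1 groups except the human knockdowns against siCTRL. Leaving out a library asks 1 direction for fewer peaks and the other for fewer absences, so such a turn may come from the setting alone. Gained regions, under 50% of changed ones in the main setting, were 54.1% for siJunb without siJunb replicate 1, 60.3% for siH1f0 without siH1f0 replicate 2, and 53.0% for siJunb against siH1f0 with the fold minimum. Induction gained regions stayed within 1.5 times of the main count under every alternative run (9964 to 19572), and lost regions did except without ground-state replicate 1 (range without 1 library 9570 to 12032). The number of lists with a shifted ratio on induction, 1 in the main setting, was 0 with the stricter threshold, with the fold minimum and with genes as the unit, 2 with absence within 500 bp and 3 with the replicate block, and 0 to 2 without 1 library. Where peaks had to cover 50% of a region it was 1, but neuronal genes in place of cardiac muscle. The adjusted p of cardiac muscle ran from 0.00522 to 0.476 over the alternatives. No paired analysis was used for the main values, since the labels do not say that equal numbers pair. The planned replicate block, which does pair them, called fibroblast and neuronal genes beside cardiac muscle, and leaves region counts identical by construction. It counts a region changed at both replicate numbers in each block, so its p-values are too small.

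Without 1 library, siJunb gained 3460 to 7132 and lost 4816 to 7304 regions, siH1f0 gained 3758 to 6989 and lost 4291 to 6981, and siJunb against siH1f0 gained 2799 to 4895 and lost 3498 to 5936. With the fold minimum, regions lost were 1704 for siJunb and 607 for siJunb against siH1f0. With crossed replicate numbers the latter comparison gave 2767 gained and 4105 lost, and the deviations of its replicates correlated across regions at r = -0.219. Without 1 library, common gained regions of the mouse knockdowns ran from 1002 to 1918 and lost from 1455 to 3769, above the main 704 and 1181, and the fold minimum gave 579 and 848. Without 1 library, the share of induction-gained regions with a peak was 72.6 to 87.3% for siJunb and 73.6 to 88.3% for siH1f0, and of lost regions 7.61 to 17.2% and 7.48 to 17.9%. With 50% cover the siJunb share of gained regions was 79.1%, from a mean of 84.3% per library. The cause of these moves was not tested, apart from the leaving out.

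In the human line, siJUNB gained 9249 to 17551 and lost 853 to 3296 regions without 1 library, siH1F0 gained 7603 to 15484 and lost 1101 to 4064, siJUNB against siH1F0 gained 5490 to 9781 and lost 3650 to 5779, and common regions were 3733 to 10544 gained and 98 to 1850 lost. Equal numbers of peaks, which remove the unequal list lengths, gave 1716 gained and 1403 lost for siJUNB, 1740 and 1287 for siH1F0, 1140 gained for siJUNB against siH1F0 (48.9% of changed regions, from 64.9%), and 686 gained and 590 lost in common. The fold minimum gave 4367 gained for siJUNB, 3263 for siH1F0, 908 lost for siJUNB against siH1F0 and 1640 gained in common, and 50% cover gave 339 lost for siJUNB. Named regions no longer called with the fold minimum were 19 of 98 on induction, 44 of 77 with siJunb and 56 of 80 with siH1f0, and with equal numbers 1, 16 and 29. Motif tests and human list tests were not run and gave no values. Depth limits the weak peaks, and the human siCTRL libraries were the shallowest of their line.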

Other observations

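Equal numbers of peaks and the pairings of libraries were planned, but their use to weigh these patterns, the splits of the 6 day 1 libraries and the genes of this first paragraph were chosen after their values were seen. On MGT induction the genes with the largest excess of gained over lost regions were Pard3b, a polarity gene, with 18 gained and 2 lost, Cdkal1 with 19 and 4, Foxn3 with 17 and 2, Arid1b with 17 and 2, and Thsd4 with 14 and 0. Lpp had 21 gained and 7 lost regions, and Hdac9, a class IIa histone deacetylase that binds MEF2 factors, had 14 and 2. The largest excess of lost regions was at Adgb and Pcnx, each with 6 lost and none gained, followed by Fam78b with 5 and none, Naaladl2 with 6 and 1 gained, and Hmcn1 with 7 and 2 gained. Igfbp3 and Ccl1 were among the genes with 4 lost and none gained. Long genes hold more regions, so these counts are not a ranking of genes by effect. With both knockdowns, Sema5a, Ccn6 and Clmp had 3 lost regions each and none gained.

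The AP-1 family had members in both directions on induction. Fos had 3 gained regions and Jdp2 1, with none lost, while Fosl2 had 3 lost and Jun 2, with none gained. Foxo1, with 6 gained and 1 lost, and Foxo3, with 4 gained, were in the senescence list, which also held Igfbp3. Il6, with 2 lost regions, and Nfkbia, with 4 gained and 1 lost, were in the inflammatory list.

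The crossed pairing of mouse siJunb and siH1f0 libraries leaves open a swap of 1 siJunb and 1 siH1f0 library. The less alike of the crossed pairs exceeded the more alike of the labelled pairs by 0.0429 in Jaccard index, a value that restates the pattern and is no separate test of a swap. Batches shared by libraries with the same replicate number would make same-number pairs alike, so they cannot give the crossed pairing. The most alike same-number pair differed from the less alike crossed pair by -0.0412, which also restates the pattern. Unequal numbers of peaks are argued against, since the excess of crossed over labelled pairs was 0.0460 with equal numbers. A batch that the labels do not give, shared by the crossed pairs, may produce the same values, and neither it nor a biological explanation was tested.

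Mouse knockdown libraries shared fewer regions with the ground state than siControl libraries did, with a mean Jaccard index of 0.567 ± 0.0132 (SD, n = 4) against 0.604 ± 0.00216 (n = 2). By library it was 0.555 and 0.557 for siJunb replicate 1 and siH1f0 replicate 2, and 0.579 for each library of the other crossed pair. The SD of the knockdown libraries thus holds the gap between the crossed pairs. The difference of 0.0372 between siControl and knockdown means was the largest in size of the 15 splits of the 6 libraries (exact permutation test, two-sided p = 0.0667, the smallest p this design allows). Unequal numbers of peaks are argued against, since with equal numbers the lowest siControl library still exceeded the highest knockdown library by 0.0241. Among regions found in siControl libraries only, 46.1% had a peak in both ground-state libraries, against at most 32.2% for the pair in any other split. This share restates the lower similarity, and splits that set knockdown libraries apart gave differences larger in size, to -45.3 points against 33.7, so it stays open whether either knockdown adds to the loss of ground-state regions, or the siControl and ground-state libraries share a batch.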
